A study of Corynebacterium glutamicum with 2 samples.

How the data were processed

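Transcript levels were measured by RNA sequencing in 2 libraries of Corynebacterium glutamicum, a soil bacterium whose outer envelope layer is built from mycolic acids. One library came from the wild-type strain ATCC13869 and 1 from strain WG001, an in-frame pks13 deletion mutant of it. Per the labels, both strains were started at an OD562 of 0.1 in 50 ml of brain heart infusion medium, grown at 30 °C, and harvested in exponential phase at an OD562 of about 7.0 (wild type) and 2.5 (mutant), and the cultures of a strain were pooled before extraction. Also per the labels, RNA was treated with DNase I, mRNA was separated from rRNA with oligo(dT) beads, and fragmented, PCR-amplified cDNA libraries were sequenced on an Illumina HiSeq instrument. Bacterial mRNA mostly lacks long poly(A) tails, and the effect of the oligo(dT) step on the values is unknown. Strand, aligner, counting tool, reference build and filters are not given in the sources used here. CASAVA 1.4 is listed per the submitters' processing notes.

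The authors deposited 1 table per library with a gene ID and an RPKM value (reads scaled to the length of the gene and the total of the library), per the file headers. The wild type table lists 2672 genes and that of the mutant lists 2685 genes; 2665 are in both, and neither table lists a gene at 0. A gene listed in 1 table only was taken as having 0 reads in the other. RPKM is a ratio of whole numbers, so the deposited values could be taken apart: for 100% of the shared genes the ratio of both libraries was, within a relative tolerance of 3e-13, a fraction of whole numbers times 1 constant. Together with the row order of the tables (descending in reads), this gave the reads and the length of each shared gene, taken as whole within 0.001 bp. For 12 of the 2665 shared genes the orders of both tables gave different counts, and the one closest to both orders was taken. The 27 genes in 1 table have no such ratio, so their reads and lengths rest on whole-length fits and row order alone and are less certain. The library totals recovered in this way were 9068590 reads for the wild type and 14262970 for the mutant. The recovered reads of the listed genes sum to 9068588 and 14262966. Totals were accepted only where this sum came close, so the closeness is in part a matter of selection. Lengths were not required to be multiples of 3, yet 100% of those of the shared genes were, so they are called coding lengths. Among the 27 genes in 1 table, 1 length was no multiple of 3. In simulated tables of 2659 genes with known answers, 99.9% of the counts and lengths were recovered. These tables were built under the same assumptions, with totals equal to the summed counts and rows in descending order of reads. These counts are used here for counting intervals and depth, and the main values rest on the RPKM as deposited.

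The main measure was log2 of (mutant RPKM + 1) over (wild type RPKM + 1), which understates the difference of genes with low values. Genes with a mean RPKM of at least 10 over both libraries were kept, and those at least 2-fold apart were counted. Each strain has 1 library, so the differences have no replicate check, and no p-value was computed. Exact 95% conditional binomial (Clopper-Pearson) intervals of the read ratio, without a pseudocount, cover counting error of these libraries only. They take each read as independent. PCR copies of a molecule cannot be told from separate molecules, so the intervals may be too narrow. Libraries were compared across genes by Pearson correlation of log2(RPKM + 1) and by Spearman correlation. In a simulation with 200 genes changed by known folds, both libraries were drawn from the wild type counts with Poisson counting error only. On 2241 genes, the 2-fold count took in 100% of the genes 4-fold higher, 100% of those 4-fold lower and 0% of the unchanged genes. The simulation held no variation between cultures or from PCR, so these are not error rates of the genes counted in the data. For genes made exactly 2-fold different, 9.52% of the higher and 95.5% of the lower ones were counted, because the abundance of other changed genes moved the median of unchanged genes to -0.13. The intervals held the true ratio for 95.6% of the genes, in counts drawn with counting error only. For the correlation between consecutive IDs, simulated blocks of 6 genes gave 0.705 over 2298 genes, and the same values without blocks gave 0.0282. Here 50 blocks were planted with a large shared shift over noise narrower than the spread of the real ratios. The value of 0.705 follows from that setting and is no benchmark for the data.

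The gene IDs are not paired with names in the tables. Of 2692 IDs, 0 were found among the identifiers of the gene table of the ASM1132v1 assembly that was used for names. Therefore results are not given for 41 gene lists fixed before the data were examined, for the deleted gene or for the genes beside it. A pairing of IDs with names through coding length and annotation order was tried in an exploratory step, and list results, values of a row taken for the deleted gene and values beside it were seen under it. It was set aside because it relies on the order of the annotation, and nothing reported rests on it. The rule for named genes, also fixed before the data were examined, then allows 2 IDs that were higher and 2 that were lower, and those at the ends of the ranking by log2 ratio were taken. Alternatives fixed in advance were pseudocounts of 0.1 and 10 RPKM, no filter, a mean RPKM of at least 50, and a 4-fold threshold. Centring on the median or on the 30% trimmed mean of the log2 ratios was also fixed in advance. So was rescaling without the 10 genes of highest RPKM in each library. Removal of the trend with coding length, the interval bound as a threshold and ratios of the named genes without a pseudocount were added after the data were seen. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.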

Results

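RNA levels of the pks13 deletion strain WG001 were compared with those of its parent C. glutamicum ATCC13869 to ask how transcript levels differ in a strain deficient in mycolic acids. pks13 encodes the polyketide synthase that joins the fatty acid chains of mycolic acids. There was 1 library per strain, made from pooled cultures, with 9068590 reads behind the wild type values and 14262970 behind those of the mutant. The strains were harvested at different densities, OD562 7.0 for the wild type and 2.5 for the mutant, so strain and density cannot be told apart in any difference between the libraries. With 1 library per strain, variation between cultures or library preparations cannot be separated from them either. No difference has a replicate check.

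The transcript profile of the mutant library differed widely from that of the wild type. Of 2298 genes with a mean RPKM of at least 10, 370 were at least 2-fold higher and 690 at least 2-fold lower in the mutant library, together 46.1% of these genes, and 1238 lay less than 2-fold apart. The excess of lower genes rests on the scaling, since with the log2 ratios centred on their median 498 genes were higher and 480 lower, and on their trimmed mean 503 higher and 478 lower. In the deposited RPKM, large differences were more often on the higher side: 42 genes were at least 16-fold higher and 11 at least 16-fold lower, and 12 were at least 64-fold higher and 3 at least 64-fold lower. At 4-fold, 154 genes were higher and 189 lower. These counts do not stand for separate events. In 4 runs of 4 or more consecutive IDs, 25 genes were at least 4-fold higher together, and 2 such runs were lower. The longest run, of 8 genes, had log2 ratios from 5.47 to 8.07. The log2 ratio of the mutant to the wild type had a median of -0.35, with 25th and 75th percentiles of -1.17 and 0.49 and 5th and 95th percentiles of -2.24 and 2.33.

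The genes with the highest ratios were Cgl0160 and Cgl0159, whose IDs are consecutive. Cgl0160 stood at 3.93 RPKM in the wild type library (54 reads) and 1328 RPKM in the mutant library (28694 reads), a log2 ratio of 8.07. Its counting interval, computed on the reads without a pseudocount, ran from 8.02 to 8.81. Cgl0159 stood at 7.88 RPKM in the wild type and 2069 RPKM in the mutant, a log2 ratio of 7.87 with a counting interval from 7.69 to 8.41.

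The gene with the lowest ratio was Cgl2871, a gene of 4833 bp coding length, rank 4 from the longest. It had 206 RPKM in the wild type from 9031 reads and 0.0580 RPKM in the mutant from 4 reads. The log2 ratio was -7.61 with the pseudocount of 1 RPKM and -11.79 without it, with a counting interval from -13.67 to -10.44. At 0.1 RPKM and 10 RPKM of pseudocount it was -10.35 and -4.42. Cgl2996 came next with the pseudocount of 1 RPKM, at 807 RPKM in the wild type (7992 reads) and 11.1 RPKM in the mutant (173 reads), a log2 ratio of -6.06 with a counting interval from -6.41 to -5.97. The order of the genes depends on the pseudocount: without one, 2 genes lay below Cgl2996, and with 10 RPKM it was the lowest, 3 genes lay below Cgl2871, and Cgl0160 had rank 3 from the highest. The sources used here do not pair IDs with gene names, so the row of the deleted gene could not be read as a check of the labels. If Cgl2871 is the deleted gene, its value measures the deletion and not a difference in transcript level, which the sources used here leave open.

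**Figure D1:**
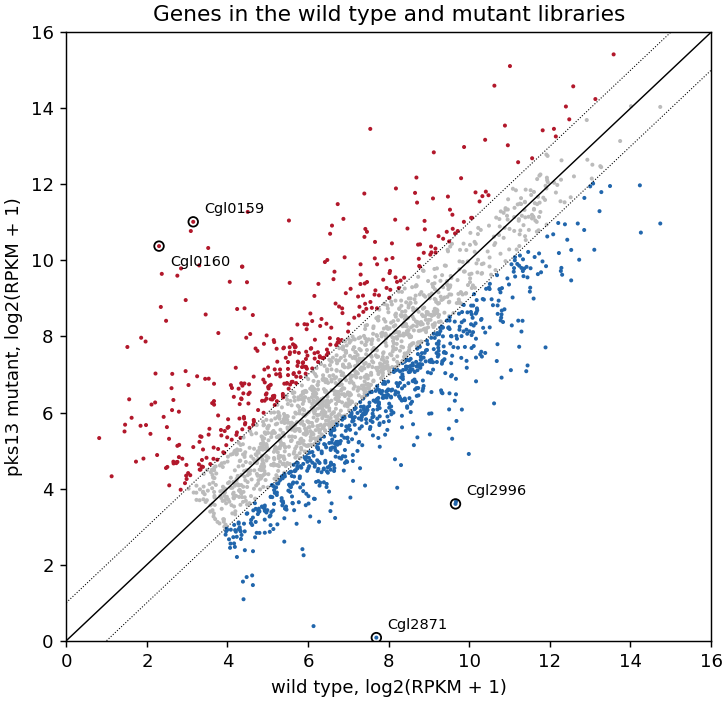
Each point is 1 of the 2298 genes with a mean RPKM of at least 10, with log2(RPKM + 1) in the wild type library on the x axis and in the pks13 mutant library on the y axis. Red and blue points are at least 2-fold higher (370) and lower (690) in the mutant, dotted lines mark 2-fold, the solid line marks equal values, and the circled genes are Cgl0160 and Cgl0159 at the top left and Cgl2871 and Cgl2996 at the bottom.

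In the deposited RPKM 65.1% of the genes at least 2-fold apart were lower in the mutant. Centring on the median, a shift of 0.35, made this share 49.1%, and centring on the trimmed mean, a shift of 0.36, made it 48.7%. Rescaling without the 10 genes of highest RPKM in each library (17 genes in all) shifted the ratios by 0.15 and gave 414 higher and 587 lower genes. These shifts all go upward, so by construction they keep every gene counted as higher. Of the 690 genes counted as lower in the deposited RPKM, 480, 478 and 587 were also counted as lower under the median, the trimmed mean and the rescaling.

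Reads were concentrated in fewer genes in the mutant library. The 10 genes with most reads held 13.3% of the reads in the wild type and 20.4% in the mutant, and 2 genes were among them in both libraries. The gene with most reads in the mutant held 6.33% of its reads and 0.403% of those of the wild type, and the gene with most reads in the wild type held 2.11% there and 0.728% in the mutant. It took 120 genes to hold 50% of the wild type reads and 76 genes to hold 50% of the mutant reads. Across genes, which are not independent replicates, the libraries correlated with a Pearson r of 0.773 for log2(RPKM + 1) and a Spearman rho of 0.778.

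The longest genes had higher ratios than the others. The genes were ranked by coding length and divided into 10 groups of similar size. The median log2 ratio was -0.59 in the shortest group (102 to 345 bp, 231 genes) and 0.13 in the longest (1671 to 8982 bp, 230 genes). From group 1 to group 7 (up to 1134 bp) the medians lay from -0.59 to -0.41 without an order by length. They were -0.22, -0.10 and 0.13 in groups 8 to 10. In the shortest group 34 genes were at least 2-fold higher and 80 lower, and in the longest 49 were higher and 34 lower. The Spearman rho of ratio and coding length across the 2298 genes was 0.144. With the mean RPKM, the ratio had a rho of -0.0496.

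**Figure D2:**
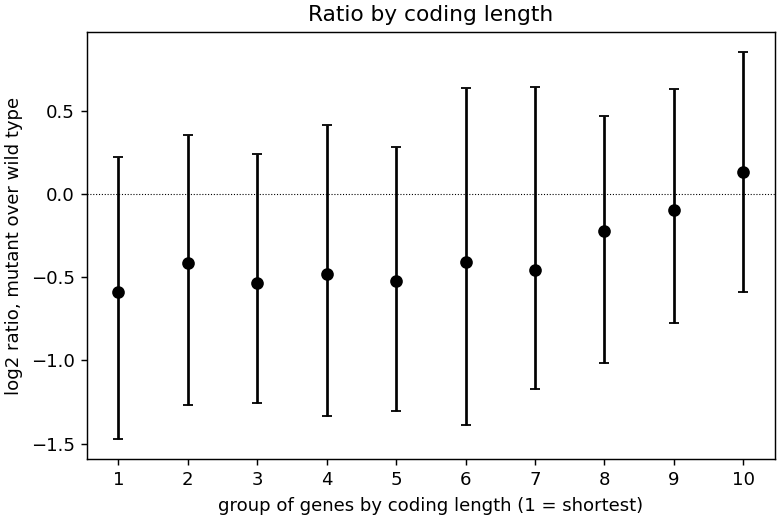
Median log2 ratio of the mutant to the wild type library (points) with its 25th and 75th percentiles over genes (bars), for 10 groups of the 2298 genes by coding length, shortest first. The median lies at -0.59 in the shortest group and at 0.13 in the longest.

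Counting error, with each read taken as independent, was small beside most of these differences. The 2298 genes that passed the filter had a median of 2384.5 reads over both libraries and no fewer than 38, and the median width of the counting interval was 0.26 on the log2 scale. With the interval bound in place of the ratio as the threshold, an alternative added after the data were seen, 324 genes were at least 2-fold higher and 587 at least 2-fold lower. Such intervals compare these libraries, not the strains, and overlapping or antisense genes cannot be told apart where strand is unknown.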

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

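Among the genes below the expression filter, which do not enter the counts of 370 higher and 690 lower genes, 20 were listed for the mutant library only. For 6 of them the mutant had more reads than 3 wild type reads would correspond to at its depth, and 3 reads was the limit set for a count of 0. This limit is approximate and makes no allowance for the 27 genes looked at. They had 7 to 33 reads in the mutant library, 1.48 to 6.99 times that limit before counting error in these reads. The 95% counting interval of the ratio to the wild type lay above equal values for 5 of the 6, with lower bounds over the 6 genes from -0.13 to 2.43 on the log2 scale. The highest value was 7.21 RPKM. In the other direction 7 genes were listed for the wild type only. By the same rule 3 of them had more wild type reads than 3 mutant reads correspond to, with 2 to 7 reads. The counting interval lay below equal values for 1 of these 3, the one with 7 reads, whose bound nearest to 0 was a log2 ratio of -1.18. Reads of genes listed for 1 library are less certain than those of the others.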

How the results depend on the processing

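Removal of the length trend, the interval bound as a threshold and named genes without a pseudocount were chosen after the data were seen. The count of genes at least 2-fold higher (370) and lower (690) stayed within 1.5 times under 18 of 20 alternative values, from 280 to 503 higher and from 478 to 748 lower. Gene totals differed between the filters, with 1677 genes at a mean RPKM of at least 50 and 2692 without a filter. By construction the stricter filter can add no gene to the counts and its absence can remove none, so both are weak checks. The 4-fold threshold gave 154 higher and 189 lower genes, fewer by its construction. Without a filter on low values the Pearson r across genes was 0.857 and the Spearman rho 0.850, and the cause was not tested. Under that setting 421 genes were higher and 748 lower. With the length trend removed 358 were higher and 672 lower, and 331 and 620 of these were among the original ones; that setting keeps the overall median by construction. The 4 named genes were chosen as the ends of the ranking, so their direction is no test of stability. Of 36 alternative values 8 moved further than from the middle to the bound of the counting interval. Their log2 ratios ranged from 6.59 to 8.43 for Cgl0160, 6.86 to 8.22 for Cgl0159, -11.79 to -4.42 for Cgl2871 and -6.18 to -5.27 for Cgl2996; the filters on low values do not enter them. The alternatives fixed for the deleted gene, the genes beside it and the gene lists are not reported, since no ID was found in the gene table and an exploratory pairing, under which such values had been seen, was set aside. With 1 library per strain no replicate could be left out. No paired analysis was possible because each strain has 1 library. Depth limits genes with few reads, and the difference between cultures of a strain was not measured.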

Other observations

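The tests of the length trend, of harvest density and of the order of the IDs were chosen only after the result was seen. Those of rescaling without the highest genes and of shared length and level were fixed before their values were known.

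Genes with consecutive ID numbers had similar ratios. Over 1997 pairs of consecutive IDs the log2 ratios correlated with r = 0.484, and where both genes of a pair were at least 2-fold apart, 423 of 497 pairs (85.1%) went the same way. No chance level was computed for this share. Since 65.1% of the genes at least 2-fold apart were lower, unrelated pairs would also often go the same way. There were 6 runs of 4 or more consecutive IDs that were at least 4-fold apart in 1 direction, 4 of them higher and 2 lower in the mutant library, with 33 genes in all. The longest run had 8 genes, among them Cgl0159 and Cgl0160. Its log2 ratios lay from 5.47 to 8.07, its wild type values from 3.93 to 21.7 RPKM and its mutant values from 801 to 2479 RPKM. A run of 7 genes had log2 ratios from 2.02 to 6.84, a run of 6 from 2.58 to 4.13, and a run of 4 from 3.67 to 6.57. The runs of lower genes had 4 genes each, with ratios from -5.75 to -2.83 and from -2.78 to -2.01.

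Chance order of the IDs is excluded for the correlation of consecutive IDs: 0 of 1000 shuffles reached it, the highest shuffle gave 0.0715, and shuffles held 0.095 runs on average and 2 at most. Shared gene length and expression level are also argued against, since r was 0.483 after the medians of 10 groups by length and 10 by mean RPKM were subtracted. A hypothesis is that consecutive IDs may mark neighbouring genes that are transcribed together. It was not tested further, because the sources used here give neither the positions of these IDs nor their transcription units, and reads shared by overlapping neighbours stay open.

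More genes were lower than higher in the mutant library, 690 against 370, in the deposited RPKM. Centring the ratios on their median (498 higher, 480 lower) or on their trimmed mean (503 higher, 478 lower) removes this excess by its construction. The 10 genes of highest RPKM in each library could not be the whole cause by the bound set in advance. Without these 17 genes the median log2 ratio was -0.20, where -0.35 was the deposited value, so this rescaling removed part of the shift. They held 13.6% of the wild type reads and 22.1% of the mutant reads, so the part of further abundant genes was not tested. A gene length trend stays open: genes longer than the median of 843 bp had 1.36 lower genes per higher gene, against 2.56 among the others, but these counts restate the trend they were chosen from and decide nothing about its part. Strain and harvest density cannot be told apart, because the strains were harvested 4.5 OD562 units apart with 1 density each. The same holds for every difference between these libraries, the runs of consecutive IDs included.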
